A study of Solanum lycopersicum with 24 samples.

How the data were processed

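Messenger RNA was sequenced from tomato (Solanum lycopersicum, cultivar Micro-Tom) anthers in 24 libraries, 4 for each combination of 3 stages and 2 temperatures. Per the labels' protocols, anthers were taken about 5 hours into a light period of 12 hours, 6 anthers were pooled per replicate, and poly-A RNA was used with a kit whose description does not state that strand was kept. Whether reads of overlapping genes on opposite strands can be told apart is therefore not known. Reads of near-identical gene copies may also not be told apart, and both kinds of genes are uncertain. Groups and replicate numbers were taken from the labels.

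The authors deposited a table of raw read counts per gene and a table of FPKM values for the same libraries. The submitters' processing notes name TopHat2 2.0.12 and HTSeq 0.6.1, and the genome build and annotation are not given in the sources used here. The count table lists 35768 gene identifiers, no line without a gene, and 6727 genes with no read in any library. The deposited FPKM values equal the counts divided by a gene length and by the library's total over genes, from which a whole-base length could be recovered for 29041 genes (tolerance 0.01 base, median 1423 bases). Library totals ranged from 15657765 to 22987661 reads. No 2 libraries of a group agreed within sampling noise, the smallest chi-square per degree of freedom over 36 comparisons being 4.63. That pair was tetrad CT replicates 1 and 2, and the other tetrad CT pairs lay at 38.0 to 56.0. Whether these 2 libraries share a source is not known.

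The reference table available (assembly SLM_r2.1, 41476 genes) matched 0 of the 35768 identifiers, so no gene is named. For this reason the gene lists, which rest on names, and the count of lists could not be tested. Genes fixed by identifier before the data were examined could have been tested. They were left out as a set because their names could not be checked. Solyc03g006880.3, which is among them, is printed below only because the rule for the largest changes chose it. In their place, genes were grouped by their change between the 2 CT stages other than the one compared, by calls at all 3 stages, and by the difference of the heat effect between stages; this grouping was chosen after the data were examined. The other designs and the alternatives listed as planned were fixed before the data were examined.

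Counts were fitted in edgeR 4.0.16 (R 4.3.3) with all 24 libraries in 6 groups, TMM scaling, the filterByExpr filter (minimum count 10), robust quasi-likelihood dispersion and 18 residual degrees of freedom. Contrasts compared LTMH with CT within each stage, the heat effect between stages, and consecutive stages within each temperature. P-values were adjusted by Benjamini-Hochberg over the 21429 genes tested in each contrast, and a gene was called at an adjusted p below 0.05 with no minimum fold. Standard errors of log2 changes were derived from the quasi-likelihood F statistic. Levels are CPM with TMM scaling. Genes printed by identifier are the 2 with the largest positive and the 2 with the largest negative log2 change in each heat contrast among called genes with a mean of at least 1 CPM over the 8 libraries and no overlap between the groups. Counting intervals of read ratios are exact 95% binomial intervals over the summed reads and cover counting error only.

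Developmental position is the projection of a library's log2 CPM (prior count 2) on the line between the means of 2 CT stages, over genes called between them with an absolute log2 change of at least 1. Differences in position were tested by two-sided exact permutation over 70 arrangements. The axis over both temperatures and the test of its span were added after the data were examined. Gene classes were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 6 tests, with an estimated correlation and fry as alternatives. Overlaps between stages are given beside the number that independent lists of the same sizes would share.

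The scripts were tested on simulated counts over 21250 genes, of which 200 were changed at each stage. Counts were drawn from stage means averaged over both temperatures and from the real library sizes. Genes were drawn independently, with each gene's dispersion shared over all stages. The wider spread of the free microspore libraries was therefore not simulated, and the shares below do not compare power between stages. For the tetrad stage 26.9% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 90.9% of those changed 4-fold were recovered; for the free microspore stage these shares were 41.8%, 58.2% and 89.4%, and for the polarized microspore stage 37.3%, 74.6% and 90.9%. False calls made up 8.21%, 4.55% and 3.57% of calls.

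Alternatives were median-of-ratios and upper-quartile scaling, DESeq2 (Wald test), limma on log2(FPKM + 1), no filter or a mean of 1 CPM, the replicate number as a block, a fit of the 8 libraries compared, a test against a log2 change of 1, and each library left out in turn. Thinning to the smallest library, a gene-length offset, developmental position as a covariate (also within the 8 libraries of a stage) and the omission of 2 free microspore libraries were added after the data were examined. Tables were summarised and drawn with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.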

Results

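The series measured mRNA in anthers of the dwarf tomato cultivar Micro-Tom, to characterise pollen abortion under prolonged high temperature. Plants either stayed at 25 °C by day and 19 °C by night with 50% relative humidity (CT) or were moved at flowering to long-term mild heat (LTMH), 34 °C by day and 28 °C by night with 68% relative humidity. Anthers were taken at 3 stages of male development, which were the tetrad stage after 4 days, the free microspore stage after 6 days and the polarized microspore stage after 8 days. At the tetrad stage the products of meiosis are still held together, free microspores have been released from the tetrad, and polarized microspores precede the division that gives pollen. Each of the 6 groups had 4 libraries, and each library was made from 6 pooled anthers. Counts per library summed to between 15657765 and 22987661 reads. Between 23457 and 25550 of the 35768 listed genes had at least 1 read. At the tetrad stage LTMH libraries held more reads than CT libraries, 19.4 ± 1.08 against 16.8 ± 0.774 M reads (SD, n = 4 each, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). At the polarized microspore stage LTMH libraries had reads in more genes, 24440.5 ± 151 against 23727.2 ± 228 (SD, n = 4 each, exact permutation p = 0.0286). There the 10 most abundant genes took 11.6 ± 0.735% of reads against 8.72 ± 0.668% (SD, n = 4 each, exact permutation p = 0.0286). These are 3 of 9 such tests, unadjusted.

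The files do not pair the gene identifiers with names, so genes are given by identifier, 2 higher and 2 lower per heat comparison, and gene groups are defined by their behaviour in these libraries. The labels do not say whether the 4 libraries of a group came from separate plants, so p-values measure the spread between these samples. Tetrad CT replicates 1 and 2 were closer to each other than any other tetrad CT pair. At that stage n = 4 may therefore overstate the number of independent controls.

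Normal development changed a large part of the anther transcriptome, and the same changes in the same direction made up most of those seen under LTMH. In CT, 4100 genes were higher and 4625 lower at the free microspore than at the tetrad stage. In the next step, 4206 were higher and 4593 lower at the polarized than at the free microspore stage (edgeR quasi-likelihood test, adjusted p below 0.05, 21429 genes tested). In LTMH the same steps called 1917 higher and 2651 lower genes, then 2598 higher and 2975 lower genes. These balances depended on the scaling. The earlier CT step had 5814 higher and 3867 lower genes under upper-quartile scaling and 5599 and 3940 in limma on log2(FPKM + 1), and the later one 4463 and 4351, and 5005 and 3507. In LTMH the earlier step had 2962 and 2324 under upper-quartile scaling and 1820 and 2635 in limma, and the later one 2852 and 2785, and 2680 and 2509. Of the tetrad to free microspore changes, 1388 genes rose and 2164 fell at both temperatures. Another 5 genes moved in opposite directions. Of the free to polarized microspore changes, 2184 genes rose and 2335 fell at both temperatures. Another 7 moved in opposite directions. Across all tested genes, which are not independent replicates, the log2 changes in CT and LTMH had a Pearson correlation of 0.803 for the earlier and 0.853 for the later step. The first principal component of the 500 most variable genes held 78.6% of their variance and the next 7.90%. The LTMH count of the earlier step fell from 4568 to 2964 without tetrad LTMH replicate 1, to 2513 without tetrad LTMH replicate 3 and to 2741 without free microspore LTMH replicate 1. Against a log2 change of 1 rather than 0, the test called 630 and 1477 genes in CT and 99 and 465 in LTMH.

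**Figure D1:**
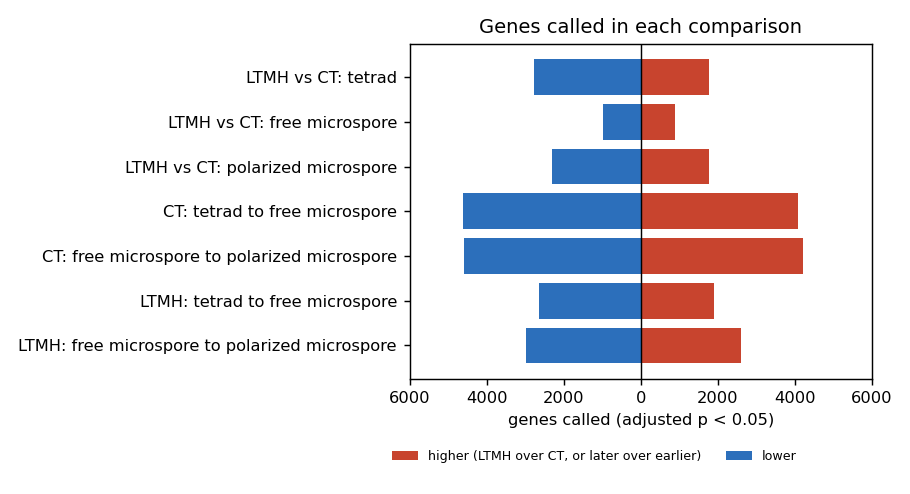
Genes called in each comparison at an adjusted p below 0.05 (edgeR quasi-likelihood test), with the number of genes on the horizontal axis, lower genes to the left of 0 and higher genes to the right. The upper 3 bars compare LTMH with CT within a stage, with 4537, 1891 and 4076 genes, and the other bars compare a later with an earlier stage within CT (8725 and 8799 genes) or LTMH (4568 and 5573 genes).

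At the tetrad stage, after 4 days of heat, 1763 genes were higher and 2774 lower in LTMH than in CT anthers. Solyc06g075880.1 rose from 0.931 ± 0.555 to 14.0 ± 4.75 CPM (SD, n = 4 each; log2 change 3.91 ± 0.76 SE; edgeR adjusted p = 0.00193). Solyc12g006360.2 rose from 1.06 ± 0.333 to 14.8 ± 1.52 CPM (log2 change 3.79 ± 0.26 SE; edgeR adjusted p = 5.05e-08). It was also higher in LTMH at the free and the polarized microspore stage. Solyc06g075880.1 was also called higher at the free microspore stage (edgeR adjusted p = 0.0271). Solyc08g008060.1 fell from 3.83 ± 1.78 to 0.0633 ± 0.0489 CPM (log2 change -5.78 ± 0.84 SE; edgeR adjusted p = 0.000202). Its 4 LTMH libraries held 5 reads together, and it was also called lower at the free microspore stage (edgeR adjusted p = 0.0264). Solyc01g008740.2 fell from 3.08 ± 0.832 to 0.113 ± 0.0851 CPM (log2 change -4.68 ± 0.93 SE; edgeR adjusted p = 0.00150). Changes were mostly moderate, with a median absolute log2 change of 0.56 over the called genes. Of these, 368 genes were at least 2-fold higher and 737 at least 2-fold lower. Every LTMH library lay on one side of every CT library for 23.2% of tested genes, against 2.86% by chance. The balance of higher and lower genes depended on the scaling. Higher genes made up 38.9% of calls as reported, 55.6% under upper-quartile scaling and 71.2% in limma on log2(FPKM + 1), where the median of all genes lay at 0.11. Without tetrad LTMH replicate 4 the test called 2973 genes. With the developmental position of each library as a covariate, a term that largely follows temperature at this stage, it called 155. Solyc08g008060.1 (log2 change -5.49 ± 1.22 SE) and Solyc01g008740.2 (-3.96 ± 1.43 SE) then had wider errors and were not called.

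At the free microspore stage, after 6 days of heat, 903 genes were higher and 988 lower in LTMH. Solyc02g087500.2 rose from 0.667 ± 0.410 to 93.7 ± 13.1 CPM (SD, n = 4 each; log2 change 7.12 ± 1.20 SE; edgeR adjusted p = 0.00115). Solyc01g108860.3 rose from 0.0740 ± 0.0582 to 2.93 ± 2.10 CPM (log2 change 5.19 ± 1.00 SE; edgeR adjusted p = 0.00290). Both genes were also higher in LTMH at the tetrad and the polarized microspore stage. Solyc10g083580.2 fell from 14.5 ± 8.86 to 0.805 ± 0.325 CPM (log2 change -4.17 ± 0.67 SE; edgeR adjusted p = 0.000702). Solyc08g080650.3 fell from 18.6 ± 15.7 to 2.15 ± 1.78 CPM (log2 change -3.11 ± 0.77 SE; edgeR adjusted p = 0.0155). This call was lost without CT replicate 4, LTMH replicate 3 or LTMH replicate 4 (log2 changes of -2.35, -2.84 and -2.79), and in a fit of the 8 free microspore libraries alone (-3.11, adjusted p = 0.0929). The median absolute log2 change of the called genes was 0.53. Of these, 250 were at least 2-fold higher and 194 at least 2-fold lower. The groups did not overlap for 12.9% of tested genes, against 2.86% by chance. The share of calls that were higher was 47.8% as reported, 58.8% under upper-quartile scaling and 70.2% in limma on log2(FPKM + 1). A fit of the 8 free microspore libraries alone called 506 genes. Leaving out LTMH replicate 1 and CT replicate 4, the library furthest along in development in each group, left 1149.

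At the polarized microspore stage, after 8 days of heat, 1782 genes were higher and 2294 lower in LTMH. Solyc11g043115.1 was almost undetected in CT, with 1 read in the 4 libraries together against 183 reads in LTMH. This is a ratio of 168 (95% counting interval 29.8 to 6684; edgeR adjusted p = 1.74e-05). Solyc09g089490.3 had 3 reads in CT and 229 in LTMH, a ratio of 70.2 (95% counting interval 23.7 to 343; edgeR adjusted p = 0.00804). Solyc03g006880.3 fell from 3.01 ± 1.54 to 0.266 ± 0.181 CPM (SD, n = 4 each; log2 change -3.50 ± 0.77 SE; edgeR adjusted p = 0.00342). Solyc05g054470.3 fell from 3.20 ± 1.84 to 0.349 ± 0.270 CPM (log2 change -3.14 ± 0.63 SE; edgeR adjusted p = 0.00156). Solyc11g043115.1 was also called higher (edgeR adjusted p = 0.0160) and Solyc05g054470.3 lower (edgeR adjusted p = 0.0112) at the free microspore stage. The share of calls that were higher was 43.7% as reported, 52.0% under upper-quartile scaling and 45.3% in limma on log2(FPKM + 1). Of the called genes, 610 were at least 2-fold higher and 331 at least 2-fold lower. The median absolute log2 change of the called genes was 0.52. The groups did not overlap for 26.2% of tested genes, against 2.86% by chance. With developmental position as a covariate, which at this stage also largely follows temperature, the test called 122 genes. Solyc09g089490.3 was then not called at a log2 change of 3.97 ± 1.10 SE (5.88 ± 1.37 without the covariate), nor, with wider errors, Solyc03g006880.3 (-2.43 ± 1.14 SE) and Solyc05g054470.3 (-4.19 ± 1.10 SE). Against a log2 change of 1 rather than 0 it called 95 genes, compared with 45 at the tetrad and 18 at the free microspore stage.

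**Figure D2:**
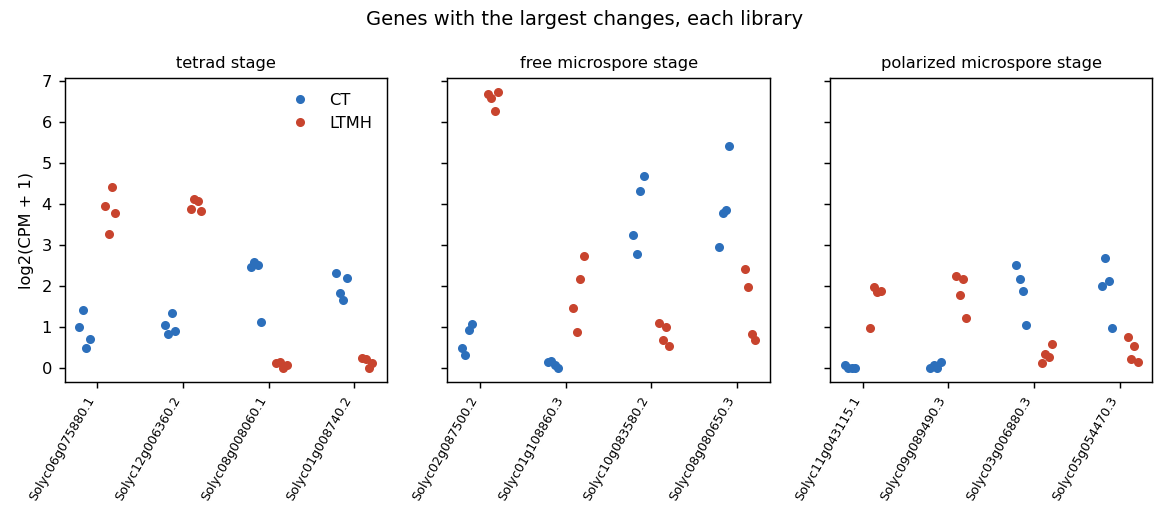
Level of each named gene in each library, as log2(CPM + 1), at the stage where the gene is named, with 4 CT libraries in blue and 4 LTMH libraries in red. All LTMH libraries lie on one side of all CT libraries for each gene, a condition of the rule that chose them, and Solyc02g087500.2 reaches the highest level, 93.7 CPM on average in LTMH.

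A set of genes responded to heat in the same direction at every stage. There were 375 genes higher and 411 genes lower in LTMH at all 3 stages, where independent lists of the same sizes would share 6.18 and 13.7 genes. The split depended on the scaling, with 483 higher and 260 lower genes under upper-quartile scaling and 516 and 183 in limma on log2(FPKM + 1). The 786 genes became 280 at an adjusted p below 0.01, 9 against a log2 change of 1, and 17 with developmental position as a covariate, which largely follows temperature at the outer stages. A fit of the 8 free microspore libraries alone called 506 genes at that stage, so the set could not reach 786 with it. The overlap with that fit was not counted. The higher set had median log2 changes of 0.63, 0.67 and 0.65 at the tetrad, free microspore and polarized microspore stage, and the lower set -0.52, -0.51 and -0.64. Within these sets, 90 higher and 54 lower genes changed at least 2-fold at all 3 stages. Between the tetrad and polarized microspore stages, 593 genes were shared among the higher calls (146.6 if independent) and 763 among the lower calls (297.0 if independent). Calls in opposite directions were fewer than independent lists would give. A total of 15 genes were higher at the tetrad and lower at the polarized microspore stage (188.7 if independent). Another 47 showed the reverse (230.7 if independent). The stages have separate control libraries, so no control is shared between these lists. They do come from 1 fit that shares each gene's dispersion over all stages. Genes with a low dispersion are easier to call at every stage, so the numbers for independent lists may be too low. Calls in opposite directions would be raised as well. Across genes, which are not independent replicates, the log2 heat changes of the tetrad and free microspore stages had a Pearson correlation of 0.581, those of the free and polarized microspore stages 0.427, and those of the tetrad and polarized microspore stages 0.292. Of 7519 genes called at any stage, 63 were called in opposite directions at different stages.

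**Figure D3:**
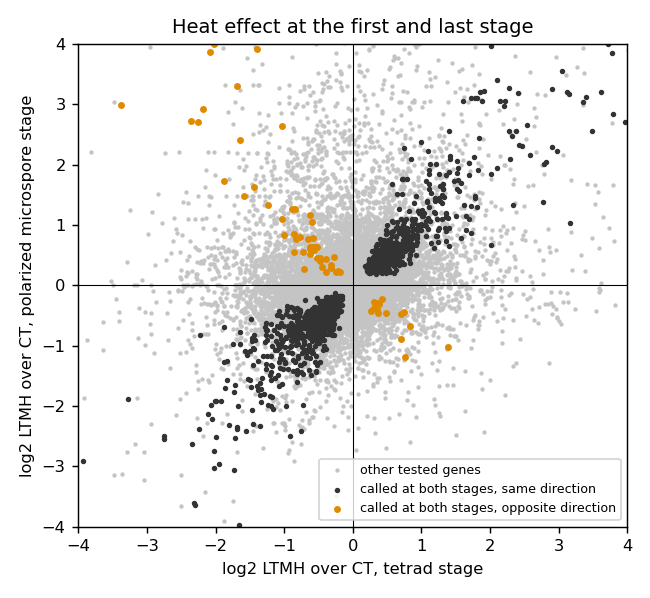
Log2 change of each tested gene in LTMH over CT at the tetrad stage (horizontal) and the polarized microspore stage (vertical), with 95 genes beyond the axes. The 1356 genes called at both stages in the same direction are in black and the 62 called in opposite directions in orange.

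The effect of heat differed between the tetrad and the polarized microspore stage for 876 genes. In 581 of them the effect was more positive at the polarized microspore stage, with median log2 changes in LTMH of -0.64 at the tetrad, -0.08 at the free microspore and 0.32 at the polarized microspore stage. Of these, 393 were called lower at the tetrad stage and 221 higher at the polarized microspore stage. A total of 508 had a lower level at the polarized microspore than at the tetrad stage when averaged over both temperatures. In the other 295 the medians were 0.29, -0.07 and -0.38. Of these, 137 were called higher at the tetrad stage and 167 lower at the polarized microspore stage. A total of 221 had a higher level at the polarized microspore than at the tetrad stage. No gene was called for a difference between the tetrad and free microspore or between the free and polarized microspore stages in edgeR, with 2201 and 1794 genes at an unadjusted p below 0.05. The smallest edgeR adjusted p-values were 0.05001 and 0.0602, just above the threshold. DESeq2 called 105 and 102, and limma on log2(FPKM + 1) called 17 and 17. For the tetrad and free microspore stages edgeR called 183 without free microspore CT replicate 2, 31 without tetrad LTMH replicate 1 and 33 with the developmental position of each library relative to its group mean as a covariate. DESeq2 called 1723 genes and limma 2296 for the difference between the tetrad and polarized microspore stages. In limma 30.3% of these were more positive at the polarized microspore stage, against 66.3% as reported. The 876 genes became 535 without tetrad CT replicate 1, 454 without tetrad CT replicate 2 and 458 without tetrad LTMH replicate 4. They became 525 and 433 without polarized microspore CT replicates 1 and 3, and 523 and 575 without polarized microspore LTMH replicates 1 and 2. Against a log2 change of 1 rather than 0, edgeR called 2 genes for this difference. With position relative to the group mean as a covariate it called 1706.

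Heat libraries lay between their own controls and the neighbouring stage at both ends of the series. Tetrad libraries were placed on the axis between the CT free microspore mean (0) and the CT polarized microspore mean (1) over 3418 genes that changed between those stages. No tetrad library shaped that axis. Tetrad LTMH libraries lay at -0.150 ± 0.0635 and CT libraries at -0.284 ± 0.0429 (SD, n = 4 each, two-sided exact permutation p = 0.0286, adjusted p = 0.0429 over 3 tests). Polarized microspore libraries, on the tetrad to free microspore axis of 2937 genes, lay at 1.29 ± 0.0403 in LTMH and 1.42 ± 0.0490 in CT (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0429). The exact permutation p rose to 0.0571 at the tetrad stage on log2(FPKM + 1), without heat-called genes and without any of 5 of the 8 libraries, and at the polarized microspore stage on the tetrad to polarized axis and without either of 2 libraries. Sign flips of same-numbered pairs gave 0.125 at both stages, the smallest that 4 pairs can give. Free microspore libraries, on the tetrad to polarized microspore axis of 6094 genes, lay at 0.498 ± 0.182 in LTMH and 0.435 ± 0.183 in CT, a difference smaller than the spread between libraries (SD, n = 4 each, exact permutation p = 0.60). On 1 axis built from both temperatures over 5657 genes, the distance from the tetrad to the polarized microspore mean was 1.13 in CT and 0.870 in LTMH. This difference of -0.260 had an exact two-sided permutation p of 0.00327 over 4900 arrangements of temperature within stage. On that axis the single stages differed by 0.150 at the tetrad stage (exact permutation p = 0.0286, adjusted p = 0.0857), 0.0758 at the free microspore stage (exact permutation p = 0.629) and -0.110 at the polarized microspore stage (exact permutation p = 0.0857, adjusted p = 0.129).

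**Figure D4:**
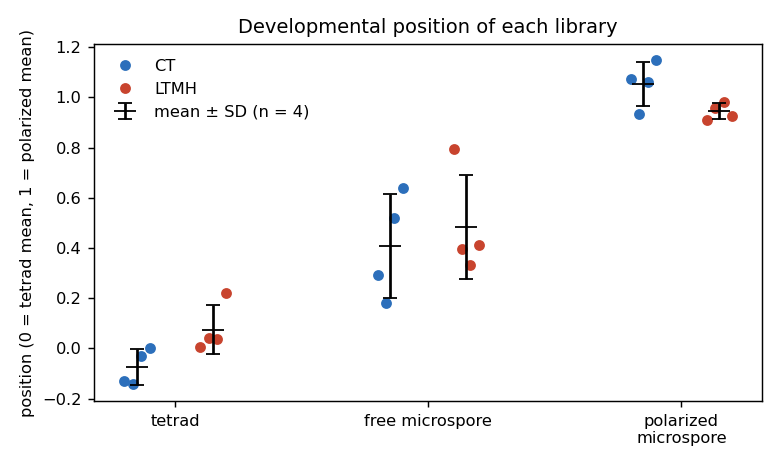
Position of each library on an axis from the mean of the 8 tetrad libraries (0) to the mean of the 8 polarized microspore libraries (1), with CT in blue, LTMH in red, and the mean and SD of 4 libraries in black. The distance between the outer stages is 1.13 in CT and 0.870 in LTMH, and the free microspore libraries spread widely, with an SD of 0.207 in CT and 0.209 in LTMH.

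Genes that fall later in CT development had, as a class, lower levels under heat at the tetrad stage, a difference that did not hold in every test. Of 2320 genes falling at least 2-fold from the free to the polarized microspore stage in CT, 373 were lower and 58 higher in LTMH at the tetrad stage, or 16.1% lower and 2.50% higher against 12.6% and 8.92% of other genes, with a median log2 change of -0.39 (camera with a preset correlation, adjusted p = 3.60e-05; adjusted p = 0.871 with an estimated correlation). Of 1098 genes rising over that step, 88 were higher and 36 lower, or 8.01% and 3.28% against 8.24% and 13.5% of other genes, with a median of 0.16 (camera adjusted p = 0.0132; adjusted p = 0.871 with an estimated correlation). At the free microspore stage, of 2118 genes rising from tetrad to polarized microspore in CT 151 were higher and 68 lower, or 7.13% and 3.21% against 3.89% and 4.76% of other genes (camera adjusted p = 0.00345; adjusted p = 0.871 with an estimated correlation). Of 3976 falling genes 49 were higher and 122 lower, or 1.23% and 3.07% against 4.89% and 4.96% (camera adjusted p = 0.0870). With each free microspore library left out in turn, the rising class lost its call in 3 of 8 fits. The falling class was called in 5 of 8 and changed direction, uncalled, in some others. At the polarized microspore stage, of 2049 genes falling from tetrad to free microspore in CT 105 were higher and 26 lower in LTMH, or 5.12% and 1.27% against 8.65% and 11.7% of other genes (camera adjusted p = 0.0338; adjusted p = 0.871 with an estimated correlation). Of 888 rising genes 59 were higher and 61 lower, or 6.64% and 6.87% against 8.39% and 10.9% (camera adjusted p = 0.895). No class was called with an estimated correlation, and 2 of the 35 splits of the tetrad libraries, the real one included, gave a gap between the falling and rising medians as large as the 0.54 observed. These classes were chosen after the data were examined and use control libraries of the other stages only.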

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

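Among the tests in this part, the profile of the genes shared by the outer stages and the position fits of single stages were set down before their values were seen; the tests of depth, of spread as the whole cause, of compressed development and of other splits, and the span of development, were chosen after the results were seen.

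Chance arrangement of the libraries is argued against for the heat effect at each stage, although 1 of 35 is the smallest share that these splits can give. Of the 35 splits of the 8 libraries, 1 gave as many genes as the 4537 at the tetrad stage, the real one, and the highest other gave 385. The same held for the 1891 genes of the free microspore stage (1 of 35, highest other 502) and the 4076 of the polarized microspore stage (1 of 35, highest other 430). It held for development in CT, with 8725 genes (1 of 35, highest other 3010) and 8799 genes (1 of 35, highest other 1835), and in LTMH, with 4568 (1 of 35, highest other 441) and 5573 (1 of 35, highest other 1392). The 876 genes whose heat effect differed between the tetrad and polarized microspore stages exceeded each of the other draws (1 of 50, highest other 12). These draws shuffled temperature within every stage, which also removed the heat effect that the stages share. They therefore cannot decide whether chance gave a difference between stages. For the other stage differences the draws decide nothing, because a count of 0 is reached by every draw (50 of 50); the draws gave up to 311 genes for the tetrad and free microspore stages and 3 for the free and polarized microspore stages. Chance cannot be excluded for the gap between the medians of rising and falling classes, which was 0.54 at the tetrad stage (2 of 35 splits as large, highest other 0.61), 0.21 at the free microspore stage (21 of 35, highest other 0.89) and 0.18 at the polarized microspore stage (10 of 35, highest other 0.28).

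In 66 groups of 4 libraries examined, 5 single libraries lay far from the rest of their group, where chance gives about 1 in 20 groups. Tetrad LTMH replicate 2 had reads in 25550 genes, the others in 24709 to 24738. Free microspore LTMH replicate 1 lay at 51.8 on the first principal component, the others at -23.5 to -15.2. Solyc08g008060.1 had 1.17 CPM in tetrad CT replicate 4 and 4.50 to 4.95 in the other CT libraries. Solyc11g043115.1 had 0.984 CPM in polarized microspore LTMH replicate 1 and 2.65 to 2.95 in the others, and 0.0490 CPM, a single read, in polarized microspore CT replicate 1.

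The 1356 genes called in the same direction at the tetrad and polarized microspore stages could reflect displaced development if heat moved both stages toward the free microspore profile. Only 29.1% of them had, over both temperatures, a free microspore level lying in the direction of the heat effect from both stages, which argues against displacement as the whole cause. It stays open as a part, since genes higher at both stages had this profile in 34.7% of cases against 21.3% of all tested genes and genes lower at both in 24.8% against 15.3%. Library depth is argued against by thinning, after which 719 genes were called the same way at all 3 stages, compared with 786. A response to temperature, or to humidity, which differed along with it, stays open and was not tested.

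The heat effect differed between the tetrad and polarized microspore stages for 876 genes, and the developmental span differed by -0.260 between the temperatures. For 83.2% of the 876 genes the sign of the difference was opposite to the developmental change averaged over both temperatures, compared with 67.2% of all tested genes and 75.3% of the 5657 genes that changed at least 2-fold with development. Depth is argued against, since 845 genes were called after thinning. Whether heat changed the pace of anther development, or anthers of slightly different age were collected at each temperature, was not tested and stays open, and either may produce these values. The tetrad stage followed 4 days of heat and the polarized microspore stage 8 days. A difference between these stages therefore cannot be told apart from one of the length of heat.

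The free microspore stage had the fewest heat calls, 1891, and the widest spread of libraries along the developmental axis. Within its 8 libraries, a term for each library's position within its group raised the calls from 506 to 903, a ratio of 1.78, which is 1.70 times the higher of the ratios at the other stages (3425 to 3585 calls at the tetrad and 4458 to 4022 at the polarized microspore stage). With this term the 903 calls were still 0.252 of the lower of those counts. This shortfall cannot decide whether spread was the whole cause, because the term removes only differences that follow position in a straight line. Spread in development between libraries stays open, as the whole cause or as a part. The same term in the fit of 24 libraries left the ratio of free microspore to tetrad calls at 0.422. This ratio decides nothing, because that fit shares each gene's dispersion over all stages and the calls rose at every stage. Depth is argued against: the ratio of free microspore to tetrad calls was 0.413 after thinning and 0.417 before. A weaker response at this stage remains open, since edgeR called no gene for a difference from the tetrad stage (2201 at an unadjusted p below 0.05) while DESeq2 called 105, limma 17, and edgeR 183 without free microspore CT replicate 2.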

How the results depend on the processing

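The thinning, gene-length and position-covariate alternatives, those of the developmental gene classes and of the span, and the omission of 2 free microspore libraries, were chosen after the data were examined. The gene lists, the count of lists and their alternatives, including the one that regresses out developmental change, were not run because the reference table available here matched none of the identifiers. Of 652 alternative values, 536 kept their direction and side of the threshold, or, for counts, a total within 1.5 times. Another 9, none of them a count, changed direction and were not called before or after. Counts were judged by their total alone, so a change in the balance of higher and lower genes does not enter these figures. At the tetrad stage 1763 higher and 2774 lower genes became 2645 and 2108 under upper-quartile scaling, and this value is among those kept. For the 12 named genes the direction was the same in every setting that tested them (a mean of 1 CPM tested 6), and calls were lost mostly against a log2 change of 1 and with position as a covariate.

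Against a log2 change of 1, the test called 45, 18 and 95 heat genes at the tetrad, free microspore and polarized microspore stages, 2 genes for the polarized minus tetrad difference, 630 and 1477 for development in CT, 99 and 465 in LTMH, and 9 genes at all 3 stages, a stricter question by construction. The 8 free microspore libraries alone gave 506 genes, 903 with their group-centred position, and 1149 genes were left by leaving out LTMH replicate 1 and CT replicate 4 from the 24. With position as a covariate 155 genes were called at the tetrad and 122 at the polarized microspore stage, and 17 at all 3 stages. In these calls the position term overlaps with temperature. The median absolute log2 change of the reported genes moved from 0.56 to 0.44 at the tetrad and from 0.52 to 0.48 at the polarized microspore stage. Of their signs, 97.8% and 99.6% were kept. The median SE rose from 0.14 to 0.23 and from 0.12 to 0.23. In the median, errors widened more than changes shrank. Which of these ended each call was not counted. Genes called at all 3 stages numbered 280 at an adjusted p below 0.01 and 144 with an absolute log2 change of at least 1.

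For the free microspore minus tetrad difference, reported as 0, median-of-ratios scaling gave 1, upper-quartile scaling 1, DESeq2 105, limma on log2(FPKM + 1) 17, no filter 1, a mean of 1 CPM 1, the block 1 and the group-centred position 33. For the polarized minus free microspore difference, also 0, upper-quartile scaling gave 1, DESeq2 102, limma 17, no filter 2, the block 18 and the group-centred position 3. The polarized minus tetrad difference of 876 became 1723 in DESeq2, 2296 in limma and 1706 with the group-centred position; the cause was not tested. In limma on FPKM the median of all genes lay at 0.11 for the tetrad heat effect and at -0.11 for this difference, so directions there are relative to that shift.

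Replicate numbers did not pair the libraries: the deviations of same-numbered CT and LTMH libraries correlated above 0.1 in 3 of 12 cases, from -0.380 to 0.351, and 2 CT libraries correlated best with their own number. The block gave 4703, 2018 and 4204 heat genes, and 1035 for the polarized minus tetrad difference. With sign flips of same-numbered pairs the position differences of 0.134 and -0.127 had an exact p of 0.125, the smallest that 4 pairs can give.

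The position difference at the tetrad stage was 0.124 on log2(FPKM + 1) and 0.101 without heat-called genes, and that of the polarized microspore stage was -0.126 on the tetrad to polarized axis, each with an exact permutation p of 0.0571; the cause was not tested. The direction of polarized microspore rising genes changed in the block (adjusted p = 0.929). With an estimated correlation the adjusted p of the called classes was 0.871, and in fry it was 0.195 for tetrad falling genes and 0.699 for tetrad rising, free microspore rising and polarized microspore falling genes.

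With each library left out in turn, heat genes ranged from 2973 to 4492 at the tetrad, 1262 to 1788 at the free microspore and 2971 to 4018 at the polarized microspore stage. Stage differences ranged from 0 to 183 (the latter without free microspore CT replicate 2), 0 to 12 and 433 to 1144. Development ranged from 6977 to 9091 and 7199 to 9354 in CT, and from 2513 to 4920 and 3825 to 5936 in LTMH. Genes at all 3 stages ranged from 591 to 770. The span difference ranged from -0.294 to -0.209. Position differences ranged from 0.105 to 0.156, from -0.0257 to 0.133 (negative without LTMH replicate 1 and, at -0.00258, without CT replicate 2) and from -0.143 to -0.104; the exact permutation p rose to 0.0571 without tetrad CT replicates 1, 2 or 4, tetrad LTMH replicates 3 or 4, polarized microspore CT replicate 1 or LTMH replicate 3. Camera adjusted p-values ranged from 0.00153 to 0.0537 (tetrad rising, lost without LTMH replicate 2), 6.99e-06 to 0.000397 (tetrad falling), 6.50e-09 to 0.480 (free rising, lost without CT replicates 1 or 2 or LTMH replicate 1), 7.81e-06 to 0.895 (free falling, called without CT replicates 3 or 4 or LTMH replicates 2, 3 or 4, and in the other direction without CT replicate 2, 0.434, or LTMH replicate 1, 0.104), 0.292 to 0.918 (polarized rising, in the other direction without CT replicate 1, 0.890, CT replicate 2, 0.918, LTMH replicate 1, 0.899, or LTMH replicate 3, 0.471) and 0.0232 to 0.0955 (polarized falling, lost without CT replicates 1 or 4 or LTMH replicate 1).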
